A study of Mus musculus with 30 samples.

How the data were processed

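Expression was read from the authors' table of intensities for 24607 probes on 18 arrays. These intensities, as deposited, were not normalized between arrays, and 30.3% to 32.3% of the values of an array were below 0, so the background had already been subtracted. The background correction planned in advance was therefore skipped, as the plan foresaw. The authors also deposited a log2 table centred on the mean of each line, made per the series design text by a cross-correlation method, and a table of log2 fold changes. The latter equals the mean of the knockdown columns minus the mean of the control columns of the former (checked, greatest difference 1e-09). Per the labels, cells were transfected with an shRNA plasmid and selected in puromycin for 3, 4 or 5 days, and XEN cells came from E4.5 blastocysts. The labels do not say which array had which selection time.

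All pairs of expression columns were compared. The ES columns labelled wild type equalled those labelled Sall4 knockdown with the same number at all 24607 probes (greatest difference 0), and any other pair of columns had at most 62 equal values. They entered once, which left 15 distinct arrays of 18. The 3 arrays stood for both groups, and the planned comparison of ES control shRNA with ES wild type was left out because it repeats the ES knockdown comparison with its sign turned. Each column of the normalized table was correlated with each intensity column of its line, after centring probes within the line, over the brightest 50% (12303 probes) and 25% (6152 probes) of the probes. In ES cells each column matched its own label (r 0.677 to 0.769, and 0.956 to 0.981 over the brightest 25%). In XEN cells each matched the column of the other shRNA group with the same number (r 0.755 to 0.915, and 0.964 to 0.998), while r with its own label was −0.44 to −0.59. The labels of the intensity table were kept and no sample was relabelled.

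Probes were named from the target numbers in the intensity table. Target numbers padded with zeros matched a mouse gene identifier in 93.3% of 9490 probes from 10000 upward, where 2.83% of whole numbers in that range are identifiers, so these were taken as gene identifiers. Unpadded numbers matched no more often than whole numbers do and were left unnamed. In addition 9 probes were named through a RefSeq accession. This named 8860 probes (36.0%) and 7390 genes, and left 15747 probes unnamed, which were tested but are not described. The probe with the highest mean stood for a gene, and other probes are given for some of the genes named. On the ChIP arrays 18517 names were found, of which 17792 matched a current symbol, 725 were kept as given and 1400 were split into a pair of genes, for 17120 genes in all, and 6318 of these were also named on the expression arrays. There were 7916 probes with coordinates in place of a name, which were left out of gene counts.

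The 15 arrays were quantile normalized together, values under a floor of 16 were set to 16, and the log2 was taken. At the floor were 41.6% of normalized values, and 5201 probes were at the floor on every array, which left 19406 tested probes with 6024 named genes. limma 3.58.1 in R 4.3.3 was used (lmFit, contrasts.fit, and eBayes with an intensity trend), with all groups in a common fit and no further terms. Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all probes of a comparison. Where all arrays of a group are at the floor a fold is a lower bound and is written as "at least". Tables were handled with the R package data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

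Gene lists were fixed before the data were examined, 17 in number. They cover pluripotency, primitive endoderm transcription factors and markers, parietal endoderm and basement membrane, visceral endoderm, trophectoderm, and mesoderm and primitive streak. Further lists hold ectoderm and neural genes, fibroblast genes, interferon-stimulated genes, p53 targets, the cell cycle, and unfolded protein and amino acid stress. The rest cover the Sall family, NuRD, Polycomb, the germ line and reference genes of stable expression. Lists with at least 5 tested members were tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01 and then with the correlation estimated, and with fry, which tests whether the list moves one way. The p-values were adjusted by Benjamini-Hochberg over lists and comparisons. Members were counted at the threshold over all probes and adjusted over the list alone. The sets of 200 genes in each direction that mark XEN or ES cells came from a limma fit of the wild type XEN arrays and the shared ES arrays alone, and their camera p was adjusted over the 4 tests, 2 sets in each knockdown.

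Named genes followed a rule set before the data were examined. It took the 10 named genes with the largest rise and the 10 with the largest fall in each knockdown comparison and in XEN against ES, among genes past the threshold whose 3 arrays of a group all lay above the 3 of the other and whose higher group mean was at or above the 60th percentile. It took 5 in each direction for XEN control shRNA against wild type and for the difference of the knockdown effects, the latter without the condition on array order. To these it added up to 3 changed members of each list, and Sall4, Pou5f1, Nanog, Sox2, Gata4, Gata6, Sox7 and Sox17, of which Nanog, Sox2 and Gata4 had a named probe. A few genes that the rule names are not reported here. For binding it took the 10 genes with the highest mean log2 ratio in each line and the 5 with the largest difference in each direction.

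ChIP-chip arrays, per the labels, compared chromatin immunoprecipitated with 10 µg of anti-Sall4 antibody, after 1% formaldehyde for 10 min and shearing to 500 bp, with 200 ng of input DNA. No control immunoprecipitation was among the samples. Per the file headers the signals came from Agilent Feature Extraction 9.1.1.1, with spatial and multiplicative detrending, linear dye normalization on rank-consistent features, and surrogate values in place of signals not above background. The deposited processed intensities of 237195 or 237185 spots per array (6301 control spots apart) were turned into log2 of immunoprecipitate over input and centred on the array's median. Surrogates made up 14.5% to 47.0% of the immunoprecipitate values of an array. Spots called outliers by the scanner software were left out. Around each probe the mean of at least 3 probes within 500 bp on either side was taken per replicate, which gave 430793 windows in ES and 430735 in XEN. A window was enriched at a mean log2 ratio of at least 1 and a one-sided limma adjusted p under 0.05, and a gene was bound with at least 1 enriched window. The difference between lines was tested two-sided over windows enriched in either line. Window means correlated between replicates with r of 0.805 to 0.891 in ES and 0.760 to 0.947 in XEN, across windows.

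Bound and changed genes were compared with Fisher's exact test, two-sided, over 5132 genes with a tested expression probe and a window, with 95% intervals and p adjusted over the 6 tests (all changed, higher and lower genes in each line). The overlap of the knockdowns used Fisher's exact test and an exact binomial test of the signs. Adjustment for the list tests of binding was over 16 lists and both lines, and for binding against cell line expression over 16 tests. The overlap test, the list tests of binding, and binding against cell line expression were added after the data were seen.

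The knockdown fits, the list test and the ChIP window calls were tested on simulated data before use. In a simulation of the ES comparison with 200 changed probes, limma recovered 58.2% of 67 changes of 1.5-fold, 83.6% of 67 changes of 2-fold and 100% of 66 changes of 4-fold. Of 181 calls, 20 (11.0%) were false, 16 of them at a log2 intensity under 6. In the XEN comparison it recovered 64.2%, 77.6% and 97.0%, and 14 of 173 calls (8.09%) were false, 11 of them under the same intensity. Of 20 simulated lists of 40 genes, the list shifted by 0.5 was found (adjusted p = 6.1e-70) and 0 others were. For ChIP windows, all 52, 48 and 50 simulated peaks with a log2 ratio of 1.5, 2 and 3 were recovered in ES, and all 50 at each size in XEN, with 0 calls away from a peak. All 34, 34 and 32 simulated differences of those sizes were recovered, and 12 of 506 calls lay away from any. The simulated spots had independent noise, with no surrogate values and no effect of probe GC content. False calls from dim spots or GC content could therefore not appear in that simulation.

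Alternatives were tried a choice at a time. For expression these were the authors' normalized table without an intensity trend, scaling to the same median, cyclic loess, dim probes left out, only the arrays of a comparison in the fit, eBayes without the trend, the replicate number as a block, each replicate left out, a 2-fold limit, the authors' rule of a mean log2 fold change of at least 1, and wild type XEN arrays as control. For binding these were normexp with an offset of 50, loess within arrays with a span of 0.3, scaling to a common median absolute deviation, windows of 250 bp, a mean log2 ratio of at least 2, adjusted p alone or under 0.01, outlier spots kept, dim input spots left out, and replicate or scan day as a block. Added after the data were seen were a floor of 32, shifted values in place of a floor, the ES or both control groups in place of wild type, the XEN labels of the normalized table, surrogate spots left out, the deposited log10 ratio of the scanner software, and centring by GC content of the probes. Omitting the background correction, which was also intended, changes nothing, because the table was already background-subtracted.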

Results

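Sall4 is a zinc finger transcription factor of the early embryo. Its role was studied in mouse embryonic stem (ES) cells of the E14 strain and in extraembryonic endoderm (XEN) cells, which are stem cells derived from the blastocyst and model the primitive endoderm. Gene expression was profiled on Illumina bead arrays in 18 samples, made up of 6 groups of 3. The groups were wild type cells, cells with a control shRNA and cells with an shRNA against Sall4, in each line. Sall4 binding was profiled by ChIP-chip, in which immunoprecipitated chromatin competes with input DNA on 2-colour Agilent promoter arrays. There were 3 ChIP replicates per line, each spread over 2 arrays, which gave 12 arrays. The mean expression intensity per array was 459 to 606 in ES cells, 1713 to 2107 in wild type XEN cells and 770.2 to 1442 in XEN cells with an shRNA. On the ChIP arrays, 52.8% to 85.4% of the spots were well above background in the immunoprecipitate channel. The number of arrays limits the precision of every value.

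Expression arrays of a group correlated closely, with a Pearson r across probes of 0.985 to 0.994, and ES arrays differed from XEN arrays with r from 0.844 to 0.883 (probes are not independent replicates). The 3 ES columns labelled wild type held the same values as the 3 labelled Sall4 knockdown at all 24607 probes, so there were 15 distinct expression arrays. These 3 shared ES arrays stood for both groups, and ES control shRNA against ES wild type was not a separate comparison. In the authors' normalized table, 6 of the 6 XEN shRNA columns correlated best with an intensity column of the opposite label, with r from 0.964 to 0.998 over the brightest 25% of probes, while 6 of the 6 ES columns matched their own label. Every direction between the XEN arrays labelled knockdown and control below follows the labels of the intensity table and turns under the labels of the normalized table. The p-values of single probes and windows measure only the spread between arrays. That spread may be technical, since the labels do not say whether replicates were separate cultures. Fisher's exact and binomial tests take genes or probes as units, and camera compares genes with genes, although these are not independent replicates.

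The comparison of the ES arrays labelled Sall4 knockdown with the ES arrays labelled control shRNA (n = 3 each) asked which genes depend on Sall4 in pluripotent cells. Sall4 itself had no named probe, nor had Pou5f1, Gata6, Sox7 and Sox17, so the depth of the knockdown was not measured here. The smooth muscle actin gene Acta2 fell by 5.07 on the log2 scale (SE 0.274, adjusted p = 1.0e-07), a 33.6-fold difference. Gata3, a transcription factor of the trophectoderm, fell 21.2-fold (SE 0.326 on the log2 scale, adjusted p = 1.5e-06), from a mean log2 intensity of 9.50 to 5.10. Krt19, a simple epithelial keratin, fell to the floor on all 3 arrays labelled knockdown (limma adjusted p = 1.7e-06). So did the caveola gene Cav1 and the AP-1 subunit Fosl2, which were at least 18.7-fold and 17.3-fold lower. Cyp1b1, Prph, Tgfb1i1, Anxa1 and Pmp22 also fell, with log2 changes of −3.96 to −3.16, and a second Tgfb1i1 probe fell by 4.57.

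Among the genes named here, the largest rise in ES cells was in Abi3, a regulator of the actin cytoskeleton, with a log2 change of 2.98 (SE 0.160, adjusted p = 1.0e-07). Fgf4, a growth factor secreted by pluripotent cells, was at the floor on the 3 control arrays and at least 5.13-fold higher on the arrays labelled knockdown (log2 change 2.36, SE 0.140, adjusted p = 2.1e-07). Vstm2l, Fastkd1, Calb2, Ly6g6d, Klk1, Fbln2, Vangl1 and Col9a2 rose by 1.92 to 2.42. Of the pluripotency regulators with a probe, Klf4 rose by 0.70 (SE 0.127, adjusted p = 0.0025). Nanog and Sox2 did not pass on the probes used, with changes of 0.30 (SE 0.328, adjusted p = 0.68) and 0.43 (SE 0.160, adjusted p = 0.11). On that Nanog probe the arrays labelled knockdown (14.14 to 14.19) all lay above the control arrays (13.74 to 14.03). Its SE came from the common fit, which also holds the XEN arrays. The other 2 Nanog probes rose by 0.97 and 1.04 and passed (limma adjusted p = 8.4e-04 and 7.0e-04), so Nanog was not shown to be unchanged. The endoderm regulator Gata4 was at the floor in both ES groups.

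By gene group, 4 of 12 trophectoderm genes fell and 0 rose in ES cells, and 6 fell when adjusted over the list alone. Krt8 fell by 2.31 and Krt18 by 2.17, both of them keratins of simple epithelia, and a second Krt8 probe near the floor did not move (−0.03). The camera test gave an adjusted p of 5.6e-04 for the trophectoderm list, and a p of 0.096 with the correlation between genes estimated, where the call was lost. The parietal endoderm and basement membrane list had 4 of 5 genes lower and 0 higher, the same 4 adjusted over the list alone, among them the laminin chain Lamb1 (−1.87), the collagen chaperone Serpinh1 (−1.55) and Fst (−1.10). Its adjusted camera p was 0.0025, and 0.046 with the estimated correlation. For p53 targets, 4 of 6 genes were lower and 0 higher, again 4 adjusted over the list alone, including the cell cycle inhibitor Cdkn1a (−0.57), Pmaip1 (−1.63) and Zmat3 (−0.74). The adjusted camera p for p53 targets was 5.6e-04, or 0.039 with the estimated correlation. None of these 3 lists turned under another scaling, where 4 trophectoderm genes and 3 p53 targets fell with arrays scaled to the same median, and 5 and 4 with cyclic loess.

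Of 16 pluripotency genes, 2 were higher and 1 lower (Lefty1, −0.57) in ES cells, and 5 higher and 1 lower adjusted over the list alone. They did not pass as moving more than other genes (limma camera adjusted p = 0.12), while fry, which tests against no change, gave them as higher (limma fry adjusted p = 1.3e-04, median 0.21). Dab2, a marker of primitive endoderm, fell by 1.68, and it was the member that changed among the 2 primitive endoderm genes tested. Of 6 ectoderm and neural genes 2 fell, Nes by 3.14 and Sox4 by 0.96 (limma camera adjusted p = 0.24). Among 7 fibroblast genes, Acta2 and Col1a1 (−1.90) fell and Fbln2 rose (1.97, limma camera adjusted p = 0.36). Of 5 NuRD genes and 7 Polycomb genes, Rbbp7 (−0.50) and Bmi1 (−1.81) fell, with an adjusted camera p of 0.27 for each list. Xbp1 was the gene of 5 in the stress list that rose (0.24, limma camera adjusted p = 0.83), and that list's median (−0.06) and mean (0.03) differed in sign. No member of the interferon (8 tested), cell cycle (12), reference (10), visceral endoderm (4), germ line (2), mesoderm (1) or Sall family (1) lists passed in ES cells, and the adjusted camera p was 0.14, 0.25 and 0.87 for the first 3 of these lists, while lists under 5 genes had no list test.

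In all, 2374 of 19406 probes (12.2%) changed between the ES groups in limma at an adjusted p under 0.05, with 1116 higher and 1258 lower on the arrays labelled knockdown. Of these, 873 changed at least 2-fold. The split moved with the scaling, to 644 higher and 1115 lower with arrays scaled to the same median, and to 318 higher and 770 lower in the authors' normalized table. Since the same arrays are also labelled wild type, the comparison may also be read as wild type against control shRNA. The knockdown columns of the authors' normalized table matched these arrays (r 0.956 to 0.981 over the brightest 25% of probes). That shows the authors used them as knockdown there, but not which label is right, as the XEN labels of that table are in doubt.

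**Figure D1:**
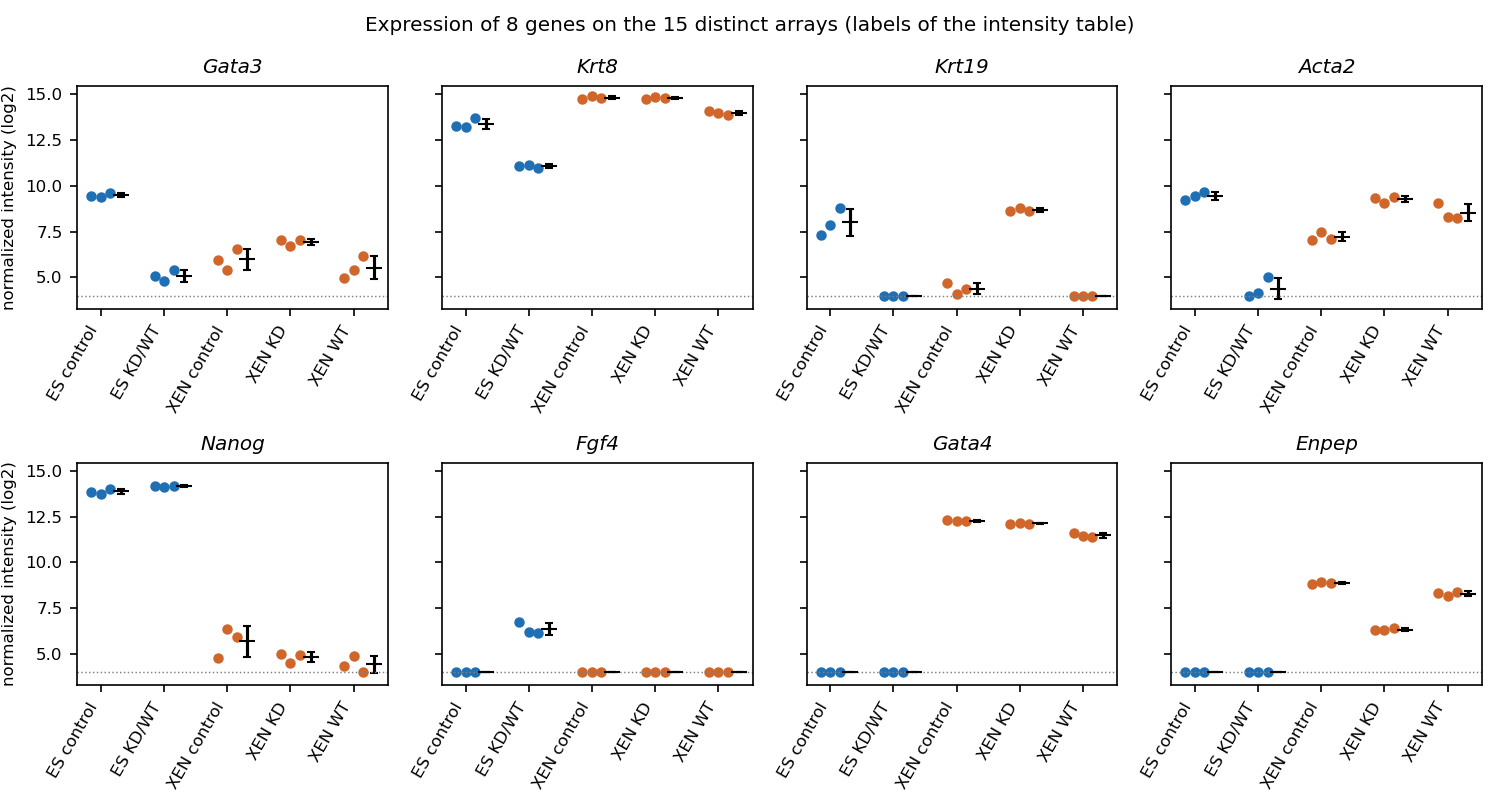
Normalized expression intensity (log2, vertical axis) of 8 genes in ES and XEN cells, where each point is an array, black bars give the mean and SD of 3 arrays in each of 5 groups, and the dotted line is the floor at 4. Gata3 stands at 9.50 on the ES control arrays and 5.10 on the ES arrays labelled knockdown and wild type, while Krt19 stands at 4.39 on the XEN arrays labelled control and 8.69 on those labelled knockdown.

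The comparison of the XEN arrays labelled knockdown with those labelled control shRNA (n = 3 each) asked the same question in extraembryonic endoderm. Krt19 was the most increased of the genes named here on the XEN arrays labelled knockdown (log2 change 4.30, SE 0.299, adjusted p = 2.0e-06), from 4.39, close to the floor, to 8.69. Bcas1 rose by 3.89 (SE 0.209, adjusted p = 2.2e-07). The keratin Krt13 was at the floor on the arrays labelled control and at least 9.61-fold higher on those labelled knockdown (SE 0.462 on the log2 scale, adjusted p = 7.2e-04). The glutathione transferases Gsta1 and Gsta2 rose by 3.18 and 3.22, the retinaldehyde dehydrogenase Aldh1a1 by 2.54, and Ccdc80, Selenbp1, Prnd and Fgd3 by 2.09 to 2.19.

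The cell adhesion gene Dscam was the most decreased of the genes named here on the XEN arrays labelled knockdown, at −2.86 (SE 0.404, adjusted p = 7.0e-04), followed by the aminopeptidase gene Enpep at −2.54 (SE 0.147, adjusted p = 4.5e-07). The haematopoietic transcription factor Runx1 fell by 1.53 (SE 0.181, adjusted p = 1.9e-04). Ppp1r16b, Ccl2, Gnai1, Ybey and Naa50 also fell, with changes of −2.20 to −1.32. The endoderm regulator Gata4 did not pass (−0.14, SE 0.0753, adjusted p = 0.36), nor did Nanog (−0.87, SE 0.328, adjusted p = 0.14), and Sox2 was at the floor in both XEN groups.

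Cell cycle genes were the list that held in XEN cells under both list tests. Of 12 members, 4 fell on the arrays labelled knockdown and 0 rose, and 6 fell adjusted over the list alone. Ccnb1 (−0.50), Plk1 (−0.46) and Mki67 (−0.35), all of them genes of dividing cells, were among them. The adjusted camera p was 0.0050, or 0.046 with the estimated correlation, and 2 members fell with arrays scaled to the same median against 3 with cyclic loess. Fibroblast genes went the other way, with 3 of 7 higher (Acta2 2.04, Col6a1 1.36 and S100a4 1.06) and 0 lower, the same 3 adjusted over the list alone. Their adjusted camera p was 0.030, and the p with the estimated correlation was 0.10, so that call was lost.

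Other lists had few changed members in XEN cells. Of 16 pluripotency genes 2 fell, including Klf5 at −0.35 (limma camera adjusted p = 0.12). Hspg2 (−0.37) fell among 5 parietal endoderm genes (0.79), and Apoa2 (−1.39) among 4 visceral endoderm genes. Sox4 rose by 0.80 among 6 ectoderm genes (limma camera adjusted p = 0.60). The trophectoderm, interferon, p53, stress, NuRD, Polycomb and reference lists had no changed member, and neither had the 4 remaining small lists. The camera p-values adjusted over all lists were 0.66, 0.12, 0.79, 0.87, 0.38, 0.56 and 0.43 for these lists in turn. Between the XEN groups, 1546 of 19406 probes (7.97%) changed, 725 higher and 821 lower on the arrays labelled knockdown, and 377 changed at least 2-fold. In the authors' normalized table, with its own XEN labels, 467 were higher and 354 lower. Which XEN group received the shRNA against Sall4 is unsettled, so each sign in this comparison may be the reverse.

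The difference between the knockdown effects in ES and in XEN cells asked whether Sall4 acts on different genes in the lines. It passed at 2381 probes, of which 1152 were higher and 1229 lower in ES relative to XEN, against 1864 probes when the XEN labels were exchanged. In the authors' normalized table, 337 were higher and 710 lower. Krt19 (−8.30, SE 0.423, adjusted p = 8.3e-08), Acta2 (−7.11, SE 0.388, adjusted p = 1.5e-07) and Gata3 (−5.35, SE 0.461, adjusted p = 7.8e-06) had the most negative differences of the genes named here under the labels of the intensity table. Anxa1 followed at −5.14 and Fosl2 at −4.26. Krt19 and Fosl2 were at the floor on all 3 ES arrays labelled knockdown, so their differences are lower bounds in size. With the XEN labels exchanged these 5 were at 0.30, −3.03, −3.46, −1.65 and −3.97, where Krt19 (adjusted p = 0.73) and Anxa1 (0.056) lost their call. The most positive differences of genes named here were those of Fastkd1 (3.32), Abi3 (2.98), Vstm2l (2.98), Dscam (2.86) and the receptor gene Notch4 (2.54), which became 1.39, 2.98, 1.87, −2.86 and 0.98 with the labels exchanged, where Fastkd1 (adjusted p = 0.28) and Vstm2l (0.17) lost their call. Abi3 was at the floor in all XEN groups, so its difference rests on ES cells alone.

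Among gene groups, cell cycle genes differed between the effects, with 3 of 12 higher in ES relative to XEN and 4 adjusted over the list alone (adjusted camera p = 0.0096, with a p of 0.062 under the estimated correlation). Pluripotency genes had 3 of 16 higher, including Fgf4 and Klf4, and 4 adjusted over the list alone (0.012, with an estimated-correlation p of 0.12). The p53 list had 3 of 6 lower (0.0081, then 0.081), and trophectoderm 3 of 12 lower (0.031, then 0.29), with 3 in each adjusted over the list alone. Each of these 4 calls was therefore lost with the estimated correlation. They also follow the XEN labels of the intensity table, and with the labels exchanged the cell cycle genes Plk1, Ccnb1 and Cdc6 turned to −0.23, −0.39 and −0.18. The trophectoderm median was −0.16, and 0.01 with cyclic loess. Parietal endoderm (2 of 5 lower), fibroblast (1 higher and 4 lower of 7), ectoderm (2 of 6 lower) and NuRD genes (2 of 5 lower) had an adjusted camera p of 0.052, 0.11, 0.22 and 0.23.

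Probes that changed in both knockdowns numbered 404, against 189.1 expected by independence (odds ratio 2.85, 95% interval 2.52 to 3.23, Fisher's exact p = 5.5e-55). Both comparisons came from a common fit, so a probe with a small spread passes more easily in each. Probes at the floor throughout a comparison cannot pass in it. An excess over independence can arise in these ways, so it does not by itself show shared targets of Sall4. Of the 404, 282 (69.8%) changed in opposite directions and 122 in the same direction under the labels of the intensity table (exact binomial p = 1.1e-15, in a test chosen after the data were seen). With the XEN labels of the normalized table, the 282 would share a direction. Over all probes tested the log2 changes had a Pearson r of −0.055 and a Spearman rho of −0.030, across probes, which are not independent replicates.

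Wild type XEN cells were compared with the shared ES arrays (n = 3 each) to set the 2 cell identities side by side. The pluripotency regulator Nanog was lower in XEN cells by a log2 change of −9.75 (SE 0.328, adjusted p = 1.9e-11), and by −6.51 and −6.85 on its other 2 probes. Dppa4 had a change of −9.76 (SE 0.120), with 2 of the 3 wild type XEN arrays at the floor, and −6.80 on its other probe. Zfp42, at the floor on all 3 wild type XEN arrays, was at least 327-fold lower. Gata4, which was at the floor in ES cells, was at least 179-fold higher in XEN cells (SE 0.0753 on the log2 scale, adjusted p = 1.6e-16). The laminin chain Lamb1 was 103-fold higher and Dab2 52.0-fold higher. Fxyd3, Rnase4, Emb, Tinagl1, Slco3a1, Cobll1 and Pth1r were higher by 6.39 to 7.67 on the log2 scale, with the ES arrays at the floor, and the change a lower bound, for all of them except Fxyd3 and Slco3a1. AF067061, Tcstv1, Tfap2c, Hspb1, Jam2, Aard and Mgmt were lower in XEN, with log2 changes of −9.08 to −8.18. Jam2 and Aard were at the floor on all 3 wild type XEN arrays, so their changes are lower bounds in size, and second probes of Mgmt, Tfap2c and Jam2 had changes of −0.72, −4.21 and −4.34. Hprt, a reference gene, was at the floor in both ES groups and at least 566-fold higher in XEN. All ES arrays came from E14 cells, so a trait of that line, for Hprt or any other gene, cannot be told from a trait of ES cells.

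Of 16 pluripotency genes, 15 were lower in XEN cells and 0 higher (16 adjusted over the list alone, adjusted camera p = 2.9e-08, and 0.017 with the estimated correlation), and 13 were lower and 2 higher with arrays scaled to the same median. All 5 parietal endoderm genes were higher, also adjusted over the list alone and under each scaling (limma camera adjusted p = 6.9e-04, then 0.039). Both primitive endoderm genes tested, Gata4 and Dab2, were higher. Trophectoderm genes were divided, with 6 of 12 higher, including Tead4 (3.76) and Krt8 (2.90, and −0.20 on a second probe near the floor), and 3 lower (0.26). Of 6 ectoderm genes, 4 were lower, among them Otx2 (−6.83) and Sox11 (−4.13), with an adjusted camera p of 0.12. Reference genes were mostly higher in XEN, 7 of 10 against 1 lower (0.040, then an estimated-correlation p of 0.29, where the call was lost), with 10 of 10 higher under scaling to the median and 3 higher and 2 lower with cyclic loess.

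The remaining lists were divided between the lines or had few changed members. Fibroblast genes had 3 of 7 higher in XEN and 2 lower, interferon genes 1 of 8 higher and 4 lower, p53 targets 2 of 6 higher and 4 lower, and cell cycle genes 4 of 12 in each direction. Stress genes had 3 of 5 higher and 1 lower, NuRD genes 2 of 5 higher and 3 lower, and Polycomb genes 3 of 7 in each direction. Their adjusted camera p ranged from 0.12 for stress genes to 0.94 for cell cycle genes. The NuRD median (−0.61) and mean (0.16) differed in sign, and camera gave fibroblast genes as higher with a mean of −0.18. Sall1, the member of the Sall family tested, was lower in XEN by 0.67 (adjusted p = 0.0013), a direction that turned to 0.66 under scaling to the median. Between the lines 11073 probes (57.1%) changed, with 5370 higher and 5703 lower in XEN, and scaling to the median gave 9286 higher and 2926 lower. That scaling moved the median of all tested probes by 0.45 on the log2 scale, and by 1.22 over the 9776 probes above the floor on every array, where quantile normalization gave −0.04. Directions between the lines are therefore relative to the whole distribution.

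XEN arrays labelled control shRNA were set against wild type XEN arrays (n = 3 each), a comparison that holds shRNA delivery together with anything else that differed between them. The antioxidant gene Srxn1 rose by 4.96 (SE 0.154, adjusted p = 4.9e-10). Gsta1 and the actin crosslinker Flnc, at the floor in wild type cells, were higher by at least 3.83 and 3.73, and Rragd and Hoxa7 by 3.71 and 3.48. Slco3a1 fell by 4.40 and the heparan sulfate proteoglycan Gpc1 by 4.19, and Gm17019, 2210409E12Rik and Pmp22 had changes of −3.84 to −3.38. Genes of dividing cells fell, 8 of 12 on the cell cycle list and 0 higher, the same 8 adjusted over the list alone, with Plk1 at −1.35, Cdc6 at −1.24 and Birc5 at −1.18. The adjusted camera p was 1.4e-04, or 0.021 with the estimated correlation, and 9 members fell under each other scaling. The p53 target Cdkn1a rose by 1.76 (SE 0.0495) and Zmat3 by 1.15, and of 6 p53 targets 3 rose and 1 fell (limma camera adjusted p = 0.065). Of 8 interferon genes 4 rose and 0 fell, with Ddx58 higher by at least 2.39 from the floor and Irf9 at 1.53 (0.15). Mesenchymal Acta2 fell by 1.30 while Col6a1 rose by 1.95, among 7 fibroblast genes of which 2 rose (0.45). The arrays labelled control here may be the knockdown, and with the XEN labels exchanged Acta2 was at 0.73 (adjusted p = 0.054).

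Some of the other lists went in both directions between XEN control and wild type arrays, and others had few changed members or none. The ectoderm median (−0.10) and mean (0.31) differed in sign. Pluripotency genes had 3 of 16 higher and 2 lower, trophectoderm 4 of 12 higher and 2 lower, NuRD 2 of 5 in each direction, and reference genes 1 of 10 in each direction. Polycomb genes had 3 of 7 lower, among them Cbx7 at −1.92 (limma camera adjusted p = 0.13). In total 6435 probes (33.2%) changed, 3243 higher and 3192 lower on the arrays labelled control, or 2374 higher and 4752 lower with scaling to the median, which moved the median of the probes above the floor by −0.28. The transfected cells were selected in puromycin for 3, 4 or 5 days, so selection and shRNA delivery were compared together. Mean intensity differed too, at 770.2 to 1442 on the arrays labelled control against 1713 to 2107 on the wild type arrays. A difference in culture or array processing between these groups therefore cannot be told apart from shRNA delivery.

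Genes that mark each line were used to ask whether a knockdown shifted cells toward the other identity. The 200 genes with the largest difference in each direction between wild type XEN and the shared ES arrays formed the sets. In ES cells, 59 of the 200 XEN genes fell and 0 rose on the arrays labelled knockdown (limma camera adjusted p = 8.1e-11 over the 4 tests, and an unadjusted p of 7.2e-05 with the estimated correlation against 2.0e-11). Of the ES genes, 37 rose and 21 fell (limma camera adjusted p = 0.0011). These sets and that comparison share the same 3 ES arrays and are not independent. With the sets drawn against the ES control arrays, both sets were lower, at a limma camera adjusted p of 0.39 and 0.47. Those sets share the 3 ES control arrays with the same comparison and are not independent of it either, so neither version decides the question in ES cells. In XEN cells, 15 XEN genes rose and 18 fell on the arrays labelled knockdown (limma camera adjusted p = 0.53), and 11 ES genes rose and 5 fell (adjusted p = 0.26).

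Sall4 binding was measured to find the promoters it occupies in each line. A gene was called bound where the mean log2 ratio of immunoprecipitate over input reached 1 in a window around a probe, at an adjusted p under 0.05. Positions are chromosome, start and end of the central probe as the array gives them, and the genome build was not given in the sources used here. In ES cells the highest window was at Mycn (chromosome 12, 13006312 to 13006368), with a mean log2 ratio of 3.29 ± 0.34 (SD, n = 3) against −0.21 ± 0.33 in XEN. The Polycomb gene Cbx7 (chromosome 15, 80018870 to 80018924) reached 2.98 ± 0.20 in ES cells and −0.05 ± 0.27 in XEN. Pluripotency genes were also high, with the ES cell F-box gene Fbxo15 at 2.81 ± 0.25 in ES and 2.16 ± 0.17 in XEN. The probe shared by Ifitm1 and Ifitm2, and 2410137M14Rik, Reep3, Ephx2, Il6st and Jam2, were at 2.70 to 3.16.

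In XEN cells the highest window was at Sec62 (chromosome 3, 30600498 to 30600557), at 3.25 ± 0.23 (SD, n = 3) against 1.98 ± 0.67 in ES. A probe between Rfc1 and Klb reached 3.18 ± 0.31, and the water channel gene Aqp8 (chromosome 7, 119562705 to 119562764) reached 2.96 ± 0.25 in XEN and −0.10 ± 0.14 in ES. Elovl5, Pik3cb, Zfp532, 2310030G06Rik, Srbd1 and the microRNA mmu-mir-181a were at 2.93 to 3.00, of which Zfp532 was also bound in ES cells, at 2.09 ± 0.41.

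Regulators of pluripotency and of primitive endoderm were fixed before the data were examined, together with the gene lists and the main settings. Sall4 bound its own gene in both lines, with the highest window at a different position in each. The ES window (chromosome 2, 168557208 to 168557256) had 2.04 ± 0.26 in ES and −0.16 ± 0.57 in XEN, while the XEN window (chromosome 2, 168561847 to 168561900) had 1.39 ± 0.15 in ES, where it was also enriched (limma adjusted p = 1.3e-05), and 2.56 ± 0.20 in XEN. Sox2 reached 2.54 ± 0.70 in ES (chromosome 3, 34453812 to 34453871) and at most 1.31 ± 0.06 in XEN, where 83.3% of the spots held substitute values for dim signal. Pou5f1 reached 1.96 ± 0.25 in ES (chromosome 17, 33605663 to 33605722) against 0.24 ± 0.13 in XEN, with 19 of 35 windows enriched in ES and 0 in XEN. Its highest XEN window (chromosome 17, 33604134 to 33604193) lay just under the limit, at 0.997 ± 0.093 in XEN against 1.52 ± 0.19 in ES. The difference there was −0.52 (limma adjusted p = 0.035), so the lack of a call in XEN depends on the limit. Gata4 was bound in XEN at 1.82 ± 0.20 (chromosome 14, 58107357 to 58107416) against 0.51 ± 0.20 in ES, a difference of 1.31 (limma adjusted p = 1.1e-04). The ES value there rests on substitute values at 100% of its spots. Gata6 was bound in XEN at 1.46 ± 0.31 (chromosome 18, 11257883 to 11257941) against 0.07 ± 0.32 in ES, a difference of 1.39 (adjusted p = 2.2e-04). Sox17 had 2 of 36 windows enriched in ES and 13 in XEN. Its highest window was the same in both lines, at 1.23 ± 0.39 and 1.45 ± 0.08, with no call of a difference (0.22, adjusted p = 0.33). Substitute values made up 66.7% of its spots in ES and 58.3% in XEN, and without them Sox17 was no longer bound in ES. Sox7 stayed under the limit in both lines, at 0.89 ± 0.07 and 1.00 ± 0.46, and Nanog had no named window.

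**Figure D2:**
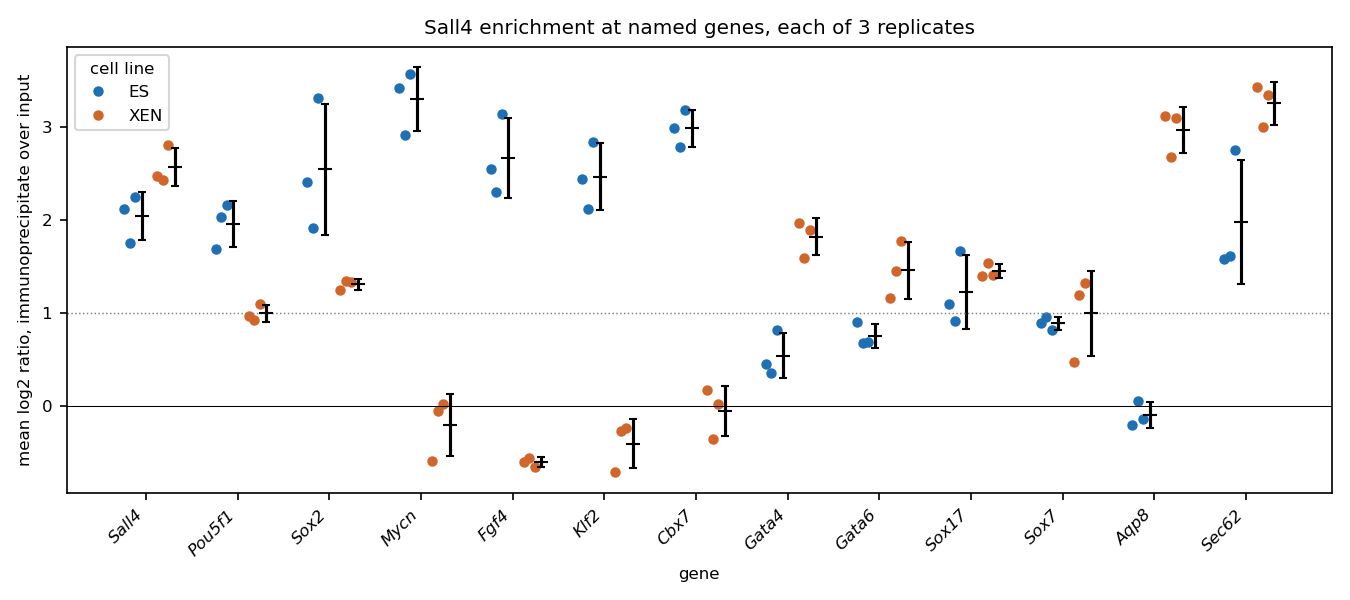
Sall4 binding (mean log2 ratio of immunoprecipitate over input, vertical axis) at 13 genes in ES and XEN cells, where each point is a replicate, black bars give the mean and SD of 3 replicates, and the dotted line marks the limit of 1. The 7 genes fixed before the data were examined show the highest window of each line and the others a window common to both lines, with Mycn at 3.29 in ES and −0.21 in XEN, and Gata4 at 0.54 in ES and 1.82 in XEN.

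The difference in binding between XEN and ES asked how far the targets are specific to a line. The greatest excess in ES was at Mycn (−3.50, XEN minus ES), followed by Fgf4 (−3.26), Cbx7 (−3.04), the transcription factor Rfx4 (−2.97) and Klf2 (−2.87). At Fgf4 (chromosome 7, 141283317 to 141283364) the ratio was 2.66 ± 0.43 in ES and −0.60 ± 0.05 in XEN. Zfp868 (3.87), 2310030G06Rik (3.56), Wdr74 (3.48), Vcpip1 (3.41) and Aqp8 (3.34) had the greatest excess in XEN. Binding differed at 4451 of 16798 genes in at least 1 window, with 3724 genes higher in XEN and 910 higher in ES, some of them in both. Without substitute values it differed at 1739 genes, with 1049 higher in XEN and 771 higher in ES. Without ES replicate 1 or ES replicate 2 the number was 2870 or 2903. Scan day was partly tied to line, since ES replicate 2 and XEN replicate 1 were the only ES and XEN replicates scanned on the same day. A fit with scan day as a term takes the difference between lines from ES replicate 2 and XEN replicate 1 alone, so no count is given for it.

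Across the genome 2811 of 16798 genes (16.7%) were bound in ES cells and 6272 (37.3%) in XEN cells, with 2091 bound in both against 1049.6 expected by independence (odds ratio 6.81, 95% interval 6.21 to 7.48). In enriched windows, 43.1% of spots in ES and 69.0% in XEN held substitutes for dim immunoprecipitate signal, against 28.9% and 30.3% in all windows. The counts with all spots, and the tests built on them, thus rest in part on dim signal, most of all in XEN. Without spots holding substitute values 1519 genes were bound in ES and 1866 in XEN, with 470 in both against 168.7 expected (odds ratio 4.46). At a mean log2 ratio of at least 2, 12 genes were bound in both against 1.66 expected (odds ratio 8.31). With arrays scaled to a common median absolute deviation 4421 genes were bound in ES and 4944 in XEN. More genes were bound in ES than in XEN with normexp (1753 against 1523) and with adjusted p alone (12603 against 11892). The ES count was 4267 without ES replicate 2 and 1315 without ES replicate 3.

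Pluripotency genes were the group most bound by Sall4 in ES cells, 24 of 31 against 5.19 expected, including Pou5f1, Sox2, Klf2, Lefty1, Tdgf1, Utf1 and Zfp42 (odds ratio 17.2, Fisher's exact adjusted p = 5.3e-12). In XEN cells 13 of 31 were bound against 11.6 expected (odds ratio 1.21, Fisher's exact adjusted p = 0.90), and 9 of 31 without substitute values (odds ratio 3.28, Fisher's exact adjusted p = 0.027). Basement membrane genes of the parietal endoderm were the most bound group in XEN cells, 12 of 15 against 5.60 expected (odds ratio 6.72, adjusted p = 0.015), and 6 of 15 in ES cells (0.18). They included Col4a1, Col4a2, Lama1, Lamb1, Lamc1, Nid1, Nid2 and Sparc. Of 10 primitive endoderm transcription factors and markers, 5 were bound in XEN, namely Dab2, Gata4, Gata6, Pdgfra and Sox17 (adjusted p = 0.90), and 2 in ES (0.90). Without substitute values the same 5 were bound in XEN, with an odds ratio of 8.02 (adjusted p = 0.017), since fewer other genes were.

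In XEN cells 13 of 20 p53 targets were bound (odds ratio 3.12, adjusted p = 0.18), and 9 without substitute values (odds ratio 6.57, adjusted p = 0.0014), among them Cdkn1a, Mdm2 and Ccng1. In ES cells 3 of 20 were. Polycomb genes bound in ES were 5 of 14 (0.32), with Cbx7, Jarid2 and Phc1 reaching a mean log2 ratio of 2 (odds ratio 38.7, adjusted p = 0.0013), against 4 of 14 in XEN. For ectoderm genes, 7 of 20 were bound in each line. The members bound in ES and XEN were 4 and 4 of 15 visceral endoderm genes, 3 and 4 of 21 trophectoderm genes, 3 and 2 of 18 mesoderm genes, and 2 and 7 of 16 fibroblast genes. They were 1 and 6 of 22 interferon genes, 2 and 7 of 23 cell cycle genes, 2 and 3 of 16 stress genes, 1 and 3 of 10 NuRD genes, 4 and 7 of 13 germ line genes, and 2 and 5 of 10 reference genes. None of these had an adjusted p under 0.05 at the limit of 1 with all spots. Without substitute values some lists passed in ES cells, with 6 of 20 ectoderm genes (Fisher's exact adjusted p = 0.028), 5 of 14 Polycomb genes (0.027) and 6 of 15 parietal endoderm genes (0.011) bound. With the scanner software's log ratio 8 of 20 ectoderm genes were bound in ES (adjusted p = 0.0014). All list tests of binding were chosen after the data were seen. They do not account for the number of windows of a gene, although a gene with more windows has more chances of a call.

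**Figure D3:**
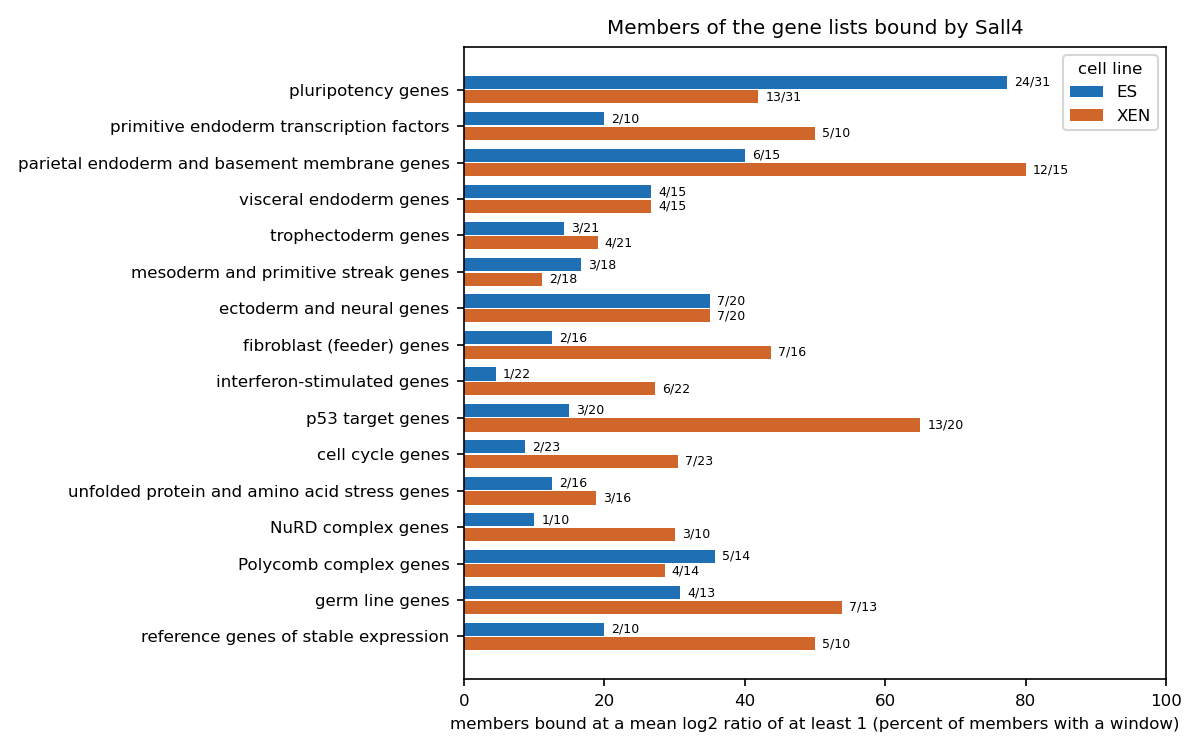
Percent of the members of each of 16 gene lists bound by Sall4 (horizontal axis) in ES and XEN cells, with bars for the percent and numbers for the members bound of those with a window. Pluripotency genes stand out in ES cells, with 24 of 31 bound, and parietal endoderm and basement membrane genes in XEN cells, with 12 of 15 bound.

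Binding and expression were joined over 5132 genes to ask whether bound genes were those that changed with the knockdown. In ES cells, 128 of 684 changed genes were bound against 117.8 expected (odds ratio 1.12, 95% interval 0.906 to 1.39, Fisher's exact p = 0.28, adjusted p = 0.44 over 6 tests). Of genes lower on the arrays labelled knockdown, 85 were bound against 67.4 expected (odds ratio 1.37, 95% interval 1.05 to 1.77, Fisher's exact p = 0.018), which did not pass after adjustment (adjusted p = 0.11). Of genes that rose, 43 were bound against 50.5 expected (odds ratio 0.818, Fisher's exact p = 0.26, adjusted p = 0.44). In XEN cells 178 of 472 changed genes were bound against 169.0 expected (odds ratio 1.09, 95% interval 0.894 to 1.34, Fisher's exact p = 0.37, adjusted p = 0.44). Without substitute values the odds ratios were 1.66 in ES (Fisher's exact p = 1.8e-05) and 1.52 in XEN (p = 0.0013). At a mean log2 ratio of at least 2 they were 2.10 in ES (Fisher's exact p = 0.083) and 2.72 in XEN (p = 8.2e-04), and among genes in the upper 50% of expression 1.31 (p = 0.045) and 1.34 (p = 0.012). Among genes changed at least 2-fold they were 1.46 in ES (Fisher's exact p = 0.019) and 0.880 in XEN (p = 0.59). Fgf4 was bound in ES (2.66) and rose, and the ubiquitin ligase gene Rlim was bound (2.30) and fell by 2.01. Ccn1, Fgfbp1, Rtn1, Cobll1 and Car3 were bound at 1.00 to 1.74 and fell, with log2 changes of −2.88 to −2.13 (a lower bound in size for Cobll1, at the floor on the arrays labelled knockdown), and Ly6g6d was bound at 1.45 and rose. In XEN cells, Krt13 (2.59), Enpep (2.09) and Aldh1a1 (2.07) were bound and changed, as were Ppp1r16b, Fgd3 and Marcks. Anxa1 and Radx in ES, and Rasgrp3, Acta2, Gnai1 and Trpm6 in XEN, were no longer bound without substitute values.

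Binding was also set against the difference in expression between the lines, in tests chosen after the data were seen. Of 83 genes bound at a mean log2 ratio of at least 2 in XEN and not in ES, 54 were higher in XEN cells against 23.6 expected (odds ratio 4.83, 95% interval 3.01 to 7.90, Fisher's exact adjusted p = 2.0e-11), and 10 were higher in ES against 26.9 expected. Of 265 genes bound at 1 or more in ES and not in XEN, 112 were higher in ES against 85.8 expected (odds ratio 1.57, adjusted p = 9.1e-04). At the same limit, genes bound in XEN alone were higher in XEN at 371 of 1219 against 346.6 expected (odds ratio 1.14, adjusted p = 0.11). That odds ratio was 2.59 without substitute values (adjusted p = 5.6e-21) and 2.32 with the scanner software's log ratio. Of 35 genes bound at 2 or more in ES alone, 15 were higher in ES against 11.3 expected (odds ratio 1.57, Fisher's exact adjusted p = 0.23).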

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

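Tests chosen only after the result was seen were those of the XEN labels, of fibroblasts in the ES cultures, of binding without surrogate spots or with scaled arrays at a mean log2 ratio of at least 1, and the counts over other splits of the arrays.

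The results here are differences between ES and XEN cells found by a test of the difference itself. The knockdown effect differed at 2381 probes, and 1 of 100 splits of the arrays, the real one, gave as many, with 1864 as the highest other, which was the split that exchanges the XEN labels. Other groupings of the same arrays within each line thus gave smaller counts. Those splits break up the effects of both lines together, so they do not test whether the effects differ between the lines. The XEN labels cannot be settled by them either. Relative to XEN, the ES effect was higher for Fastkd1 (3.32 on the log2 scale), Abi3 (2.98), Vstm2l (2.98), Dscam (2.86) and Notch4 (2.54), and lower for Krt19 (−8.30), Acta2 (−7.11), Gata3 (−5.35), Anxa1 (−5.14) and Fosl2 (−4.26). With the XEN labels exchanged these were 1.39, 2.98, 1.87, −2.86 and 0.98, and 0.30, −3.03, −3.46, −1.65 and −3.97. Fastkd1, Vstm2l, Krt19 and Anxa1 then lost their call, and Dscam turned. Krt19 and Fosl2 were at the floor on the ES arrays labelled knockdown, so their differences are lower bounds in size and Krt19 has no settled sign under the exchange. Dscam was at the floor on all ES arrays, and its difference is the XEN effect alone. Among list members it was higher for Fgf4 (2.36), Klf4 (0.98), Apoa2 (2.47), Fbln2 (1.97), Plk1 (0.68), Ccnb1 (0.62) and Cdc6 (0.50), where the exchange turned Apoa2 to −0.31, Plk1 to −0.23, Ccnb1 to −0.39 (adjusted p = 0.041) and Cdc6 to −0.18, and left Klf4 at 0.43 (adjusted p = 0.18). It was lower for Dab2 (−1.62), Fst (−1.73), Serpinh1 (−1.45), Krt18 (−2.31), Krt8 (−2.31), Nes (−2.74), Sox4 (−1.77), Col1a1 (−2.76), Pmaip1 (−1.63), Zmat3 (−0.65), Cdkn1a (−0.61), Rbbp7 (−0.88) and Mta3 (−0.57), of which Fst, Sox4, Col1a1, Rbbp7 and Mta3 kept their sign but not their call under the exchange. Abi3, Fgf4, Fbln2 and Pmaip1 were at the floor on all XEN arrays.

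Sall4 binding differed at 4451 genes, with XEN minus ES at 3.87 for Zfp868, 3.56 for 2310030G06Rik, 3.48 for Wdr74, 3.41 for Vcpip1 and 3.34 for Aqp8, and at −3.50 for Mycn, −3.26 for Fgf4, −3.04 for Cbx7, −2.97 for Rfx4 and −2.87 for Klf2. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The highest other split gave 0 genes against 4451 here, 54 probes against 2374 for the ES knockdown, 16 against 1546 for the XEN knockdown, 1 against 11073 for XEN against ES, and 8 against 6435 for XEN control against wild type, so that 1 split reached each real count.

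The XEN knockdown and control columns stand for each other in the 2 expression tables of the authors. All 6 XEN columns of the normalized table correlated best with an intensity column of the other label, which fits an exchange of labels in either table. The wild type XEN arrays lay nearer to the arrays labelled control at 70.4% of the 1546 probes that separate the shRNA groups. That is what correct labels in the intensity table would give if a control resembles wild type more than a knockdown does, but a knockdown that moves XEN cells toward the wild type state may give it too, so the tables cannot be told apart on this ground. No Sall4 probe was named, and the direction in XEN stays open.

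Gata3, Acta2 and the keratins Krt8, Krt18 and Krt19 were lower on the ES arrays labelled knockdown, which are also the arrays labelled wild type. If those arrays are untransfected cells, ES control minus these arrays and XEN control minus wild type would both measure shRNA delivery. Of the probes changed in both, 63.3% had the same sign, between the limits of 50% and 65% set before the test. If the XEN labels are exchanged, the arrays labelled knockdown are the control and the share is 65.4%, just past the upper limit. The outcome thus turns on the unsettled XEN labels, and a wrong label and a Sall4 effect cannot be told apart. Fibroblasts in the ES control cultures are a candidate explanation for Acta2, but 2 of the 7 fibroblast genes tested were lower and 1 (Fbln2) was higher, which decides nothing. A loss of differentiated cells upon knockdown, the biological explanation that the design offers, stays open and untested.

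More genes were bound in XEN than in ES, with a ratio of 2.23 at a mean log2 ratio of at least 1 (6272 against 2811). Its size depends on single ES replicates, since the ES count was 4267 without ES replicate 2 and 1315 without ES replicate 3. Without surrogate spots the ratio was 1.23, and with arrays scaled to a common median absolute deviation it was 1.12. Dim spots or a wider spread on the XEN arrays may thus explain most of that excess. The direction turned with normexp (1753 genes in ES and 1523 in XEN) and with adjusted p alone (12603 and 11892). At a mean log2 ratio of at least 2 the ratio was 1.93, and 1.88 without surrogate spots (123 genes in ES and 231 in XEN), which argues against surrogates as the source of the excess among strong sites. A difference in Sall4 binding between the lines remains open for those sites, as does the spread of the arrays.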

How the results depend on the processing

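Alternatives chosen only after the result was seen were the floors, the control groups in place of wild type, the exchanged XEN labels, the marker sets from ES control arrays, the scanner log ratio, surrogate spots left out, GC centring, and the odds ratios under binding alternatives other than a mean log2 ratio of at least 2 and adjusted p alone. The cause was not tested for any change below unless stated. Array signal over background limits the dim genes, since 41.6% of normalized expression values were at the floor and up to 47.0% of immunoprecipitate spots held surrogates. The alternative without background correction and ES control against wild type were not run, as the table was already background-subtracted and the columns were identical.

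Requiring 2-fold changes left 873 probes in the ES knockdown, 377 in the XEN knockdown, 1049 in their difference, 6916 in XEN against ES and 2330 in XEN control against wild type, by its construction. The authors' normalized table gave 1088, 821 and 1047 for the knockdowns and their difference, and the authors' rule gave 334 and 260. Wild type as the XEN control gave 6845, with Ccl2 at 0.73, Gata4 at 0.64 and Nanog at 0.39. Leaving out a replicate gave 1859 to 2395 probes in ES and 1090 to 1576 in XEN.

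The normalized table turned the sign of XEN genes, as its XEN shRNA labels are opposite to those of the intensity table. In the XEN knockdown it gave Krt19 −3.17, Bcas1 −2.46, Krt13 −1.78, Gsta2 −2.91, Gsta1 −2.88, Aldh1a1 −2.66, Ccdc80 −1.96, Selenbp1 −1.98, Prnd −1.91, Fgd3 −0.76, Sox4 −0.69, Acta2 −1.87, Col6a1 −1.20 and S100a4 −1.01. It gave Dscam 2.85, Enpep 2.72, Ppp1r16b 1.22, Ccl2 1.42, Gnai1 2.17, Runx1 1.74, Ybey 1.19, Naa50 0.90, Gata4 0.23, Nanog 0.57, Klf5 0.37, Hspg2 0.39, Apoa2 0.41, Ccnb1 0.56, Plk1 0.51 and Mki67 0.43. In the difference it gave Fastkd1 −0.14, Dscam −2.86, Krt19 1.65, Plk1 −0.28, Ccnb1 −0.51 and Cdc6 −0.36. Exchanged XEN labels gave Dscam −2.86, Krt19 0.30, Apoa2 −0.31, Plk1 −0.23, Ccnb1 −0.39 and Cdc6 −0.18 in the difference, and Acta2 0.73 in XEN control against wild type. In XEN against ES, ES control arrays gave Acta2 −0.94, both control groups gave Acta2 −2.24 and Ddx58 1.43, and scaling to the median gave Tubb3 0.13, Sall1 0.66 and Chd4 0.40.

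For the marker sets, XEN genes in the XEN knockdown turned upward with 400 genes (p = 0.764) and in the authors' table (0.186), where ES genes turned downward (0.0311). With fry the sets passed in XEN at 0.0159 and 0.0253. Sets from ES control arrays gave 0.0969 and 0.355 in ES. With fry the direction of the list turned for interferon genes in the difference (adjusted p = 0.942), fibroblast genes in XEN against ES (3.9e-08), stress genes (0.804) and reference genes (0.629) in XEN control against wild type.

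Genes bound in ES, bound in XEN and differing numbered 12603, 11892 and 8643 by adjusted p alone, 1554, 2287 and 2461 with GC centring, 120, 232 and 328 at a mean log2 ratio of at least 2, 1753, 1523 and 2453 with normexp, 1502, 2024 and 2401 without dim input spots, 1519, 1866 and 1739 without surrogate spots, 1483, 2346 and 2741 with the scanner log ratio, and 127, 318 and 411 with that ratio at 2 or more. Scaling to a common median absolute deviation gave 4421 in ES and 2964 differing, loess 3152 in XEN, and windows of 250 bp 5453 in ES. Scan day as a term left the difference to a single replicate of each line, so no count is given for it. Leaving out a replicate gave 1315 to 4267 bound in ES (1315 without ES replicate 3) and 2870 to 6422 differing. The Gata4 value in ES was −0.044 with GC centring, −0.15 with normexp and −0.16 with the scanner log ratio.

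Odds ratios of bound among changed genes, for ES, for genes higher in ES and for XEN, were 1.58, 1.19 and 1.65 with loess, 1.57, 1.48 and 1.55 with GC centring, 1.70, 1.30 and 1.66 with normexp, 1.70, 1.22 and 1.503 without dim input spots, 1.66, 1.18 and 1.52 without surrogate spots, and 1.72, 1.28 and 1.52 with the scanner log ratio. At a mean log2 ratio of at least 2 they were 2.61 for genes higher in ES and 2.72 for XEN, and 2.32 and 2.75 with the scanner log ratio. With adjusted p alone, genes higher in XEN had 0.996. Among 2-fold changes the ratios were 1.46 in ES, 1.15 for genes higher in ES, and 0.880, 0.872 and 0.895 for XEN, its higher and its lower genes. Among genes in the upper 50% of expression they were 1.31 in ES and 1.34 in XEN. Leaving out a replicate gave 1.05 to 1.502 in ES, 0.766 to 1.37 for genes higher in ES, 0.962 to 1.20 in XEN and 0.807 to 1.10015 for genes lower in XEN.

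The replicate number as a block gave 2259 probes in ES, 1456 in XEN, 2212 in the difference, 11008 in XEN against ES and 6308 in XEN control against wild type, with 4197 genes differing in binding and an odds ratio of 0.979 for genes lower in XEN. The pairing check gave r of −0.14 to 0.07 between arrays with the same number, so the numbers did not pair the arrays, and −0.28, 0.09 and −0.05 between ES and XEN binding.

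Of the other values, named expression genes kept their call in 1702 and lost it in 65 with the same sign, and with a replicate left out in 1280 and 57. Binding of named genes kept its call in 702, lost it in 97 and gained it in 12, and with a replicate left out it kept its call in 159 and gained it in 3. Gene lists kept their call in 144, gained it in 25 and lost it in 7.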

Other observations

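Tests of list binding, of the overlap of the knockdowns and of binding against cell line expression were chosen only after the result was seen, as was the share of probes by wild type position.

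In ES cells the 11 pluripotency genes with a mean log2 ratio of at least 2 were Dppa4, Dppa5a, Fbxo15, Fgf4, Gdf3, Jarid2, Klf2, Mycn, Nr0b1, Sox2 and Tdgf1, against 0.221 expected (odds ratio 83.8). In XEN cells the parietal endoderm genes Col4a1, Lama1, Lamb1, Nid1 and Serpinh1 reached the same limit, against 0.207 expected (odds ratio 36.4, adjusted p = 2.1e-05). In ES cells 2 of the 15 genes on that list, Lama1 and Nid2, reached it too, against 0.107 expected (odds ratio 21.7, Fisher's exact adjusted p = 0.040), so Lama1 did in both lines.

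The p53 target Cdkn1a and cell cycle genes differed between transfected and wild type XEN cells. Cdkn1a was 1.76 higher and Plk1 1.35 lower on the arrays labelled control than on wild type arrays, and Cdkn1a was also 0.57 lower on the ES arrays labelled both knockdown and wild type than on the ES control arrays. Among probes changed in both, the XEN arrays labelled knockdown, set against wild type, had the same sign as ES control minus the shared ES arrays at 65.4% (835 of 1277), and the XEN arrays labelled control at 63.3% (725 of 1146).

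At the probes that separate the XEN shRNA groups, the wild type arrays lay at a root mean square distance of 0.945 from the arrays labelled control and 1.37 from those labelled knockdown. The share of probes nearer to control was 70.4%, 70.1% and 71.2% for wild type replicates 1, 2 and 3.

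Enriched windows held more surrogate spots than all windows together, 43.1% against 28.9% in ES and 69.0% against 30.3% in XEN, and their probes were lower in GC content, at 39.0% in ES and 35.5% in XEN against 42.5%.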
